A study of Drosophila melanogaster with 2 samples.

How the data were processed

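Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on whole Drosophila melanogaster embryos of both sexes collected 0 to 24 h after egg laying. The embryos came from a transgenic line that stably makes Max, a basic helix-loop-helix leucine zipper protein and the DNA-binding partner of Myc, with GFP fused to its C terminus. Per the labels, the IP used an antibody against GFP, and chromatin had been sonicated to a size range of 200 to 800 bp. The labels give 1 group of 2 biological replicates, numbered 2 and 3, with 1 library each. No second group exists in this series, so no comparison between conditions was made, and the comparisons below are between replicates, between sites and between groups of genes.

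The authors deposited narrowPeak lists for each replicate, for the pooled replicates, and for the pooled peaks that passed a threshold on the irreproducible discovery rate (IDR). The IDR is an estimate, from 2 ranked lists, of the rate of peaks that are not reproducible among those called. Per the text listing deposited beside each sample, each list was made from IP alignments against a control alignment, and was given on the assemblies dm6 and dm3. The control itself was not analysed here. The aligner and the peak caller are not given in the sources used here. The peak score in the lists deposited by the authors ranks peaks by enrichment over the control on a scale of its own for each list, so scores were used only to rank or describe peaks within a list. The lists deposited by the authors also hold −log10 of the peak caller's q-value, which ran from 2.74 to 3.58 in the dm6 IDR list, and the offset of the summit from the peak's start. No p-value was given for single peaks.

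Each replicate list and each pooled list held exactly 30000 peaks, so these lists were capped and their lengths carry no information on the yield of a library. The lists hold no read counts, so the sequencing depth of the libraries is unknown here. The IDR list held 4712 peaks on dm6 and 4438 on dm3. On dm6 all 4712 IDR peaks were also in the pooled list, and exactly 4712 pooled peaks had a score at or above the lowest IDR score, so the IDR list is the top of the pooled list and not a test of each site in each replicate. The same held for all 4438 peaks on dm3. In the dm6 IDR list 15 rows repeated an interval with another summit, which left 4697 distinct intervals, and each row was treated as a summit. The summit lay at the midpoint of the peak for 75.8% of the IDR peaks, and the median peak width was 436 bp.

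Positions were set against the Ensembl annotation of Drosophila melanogaster, release 115, and the Release 6 genome sequence, whose arm lengths and names fit the dm6 lists. The dm3 lists were used only for counts and overlaps, because no dm3 reference was used here and no coordinate was converted. Analyses against the annotation used the 6 main arms X, 2L, 2R, 3L, 3R and 4, with 13945 protein-coding genes. Coordinates are given 1-based on dm6.

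A promoter peak is a peak with its summit within 500 bp of an annotated transcript start of a protein-coding gene. Replicate overlap was counted at a minimum of 1 bp between the N highest-scoring peaks of each replicate, with N = 4712. Overlap and promoter shares were compared with 1000 circular shifts of the peaks within each arm (one-sided permutation test, smallest possible p = 0.001). Motifs were counted within 50 bp of the summit and in windows of equal width centred 500 bp to each side, and compared by the exact two-sided McNemar test against each flank. The larger of the p-values was kept and adjusted by the Benjamini-Hochberg method over 11 motifs. Gene lists were compared with all other protein-coding genes by the two-sided Fisher exact test with Benjamini-Hochberg adjustment over 31 lists and a threshold of 0.05. Arm shares of X and 4 were compared with the arms' shares of promoters by an exact two-sided binomial test, with starts within 500 bp of each other merged into 1 promoter. Shares carry 95% Wilson intervals. Peaks and genes are not independent replicates, so these intervals and p-values describe counting error over sites and not the spread between embryos.

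The grouping, the tests, the 31 gene lists, the motifs and the alternatives were fixed before the data were examined, except where a choice is said to be later. Chosen after the data were seen were the ranks of motifs among palindromes of equal GC count and among octamers, the E-box test of promoter against other peaks, the DRE and Ohler 1 by score, the places of summits other than promoters, the distances of summits from starts, GC content, the arm shares of 2L, 2R, 3L and 3R, and the comparisons with the lowest-ranked pooled peaks. For 5 names on the lists no gene was found in the annotation: Mak16, sop, Atic, dys and nos. Genes were named by a rule fixed at the same time. It takes the 10 highest-scoring IDR peaks at promoters, up to 3 members of each list that passed its test and up to 1 of each other list, all members of the Myc-Max network, and the 5 promoter peaks with the largest rank difference toward each replicate. A gene that the rule takes in is not reported here. Alternatives were other promoter windows, other motif windows, the higher-scoring part of the IDR list, the pooled list, each replicate alone, dm3, other backgrounds and other rules of overlap. With 1 replicate left out, the 4712 highest-scoring peaks of the other replicate took the place of the IDR list.

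Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The tests were also run on simulated data. Of 100 simulated lists of 40 genes with 60% of members bound, 97 passed as higher among the 13945 genes, and none of 100 random lists passed. Smaller lists and lists with a lower share bound were not simulated, so this rate does not carry over to them. For the promoter share, 5 of 100 random placements of 4712 summits gave p under 0.05. All 108 E-boxes planted among 1000 random windows were found, which checks the search for the sequence only.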

Results

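Max-GFP binding was mapped in whole embryos as lists of ChIP-seq peaks from 2 biological replicates, numbered 2 and 3. The peak lists carry the authors' scores and no read counts, so depth is unknown. The IDR-thresholded list on dm6 held 4712 peaks with scores from 87.0 to 1561.5 and a median of 136.4.

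Which genes carry Max-GFP at their promoters was the first question. Max-GFP peaks were found at the promoters of 3613 of 13945 protein-coding genes (25.9%), and among the fixed lists nucleolar ribosome biogenesis and cytoplasmic ribosomal protein genes carried them most often. Of the 40 nucleolar ribosome biogenesis genes, 36 had a promoter peak (90.0%, 95% Wilson interval 76.9 to 96.0), as did 74 of the 86 cytoplasmic ribosomal protein genes (86.0%, 77.2 to 91.8). The lowest shares were 1 of 114 cuticle genes, 1 of 230 chemosensory receptor and odorant-binding genes, and none of 20 antimicrobial peptide genes, for which the interval reaches 16.1%. Of the 31 lists, 12 lay above the other genes, 7 lay below, and 12 did not pass the test. A summit within 500 bp of starts of several genes counts for each of them and for each of their lists. Many of the peaks named below have such a neighbour, and only some of the neighbours are named. With shared promoters counted once, 11 of the 12 lists still lay above.

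**Figure D1:**
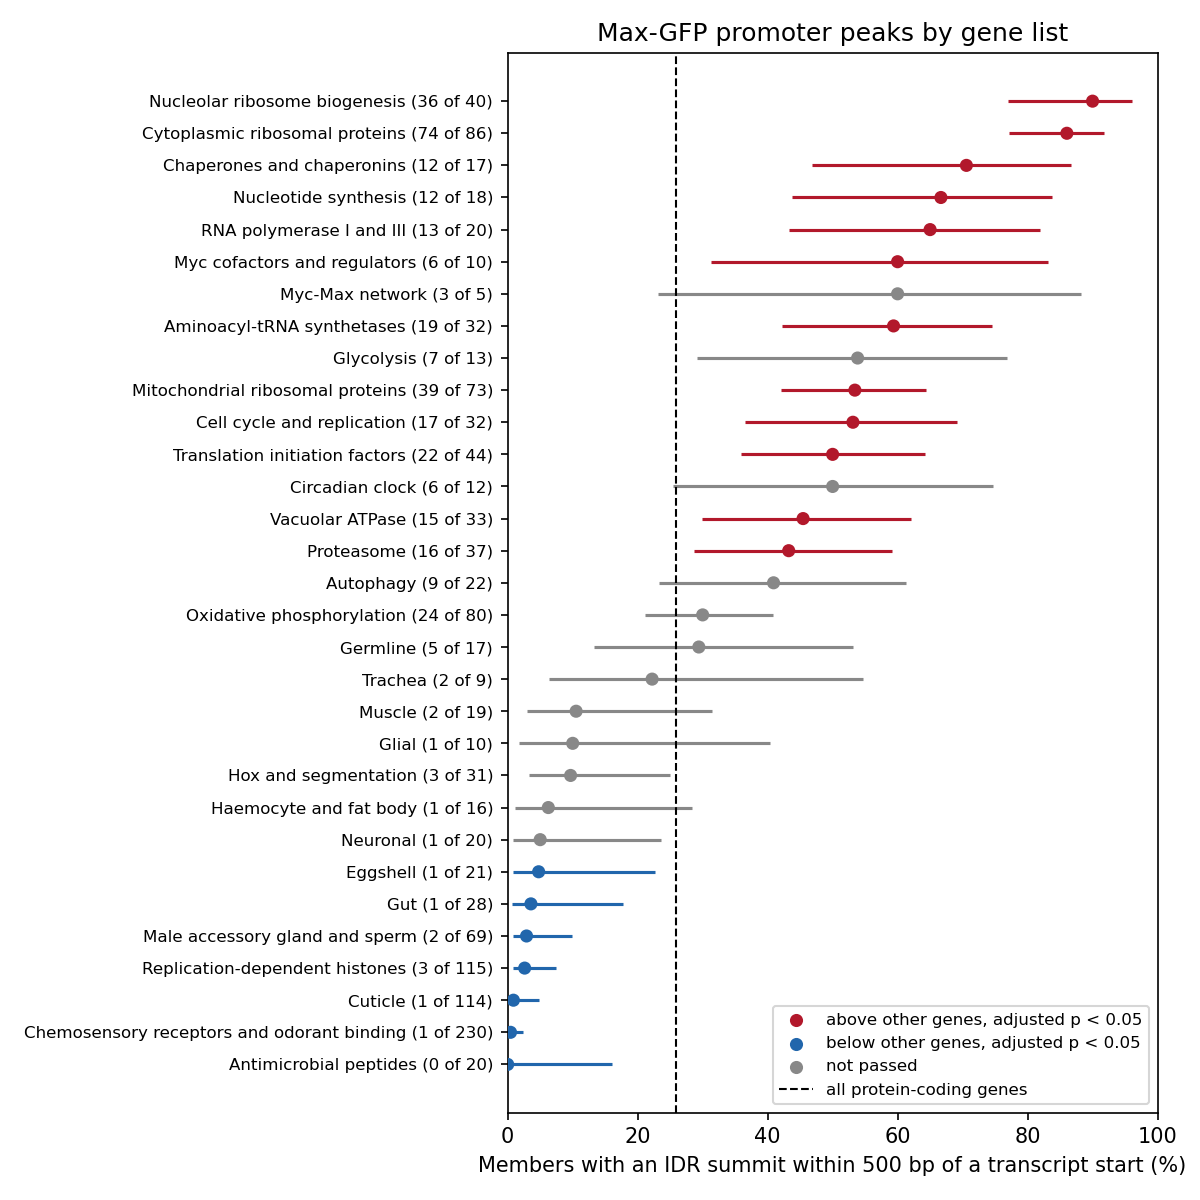
Share of the members of each gene list with an IDR summit within 500 bp of a protein-coding transcript start, in percent (x axis), with 95% Wilson intervals, and the counts beside each name. The dashed line marks the 25.9% of all protein-coding genes; nucleolar ribosome biogenesis lies at 90.0% and cuticle genes at 0.877%.

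Among ribosome biogenesis genes the highest scores were at RIOK1, a kinase of small-subunit maturation, with a score of 682.1, at Nop56, a core protein of box C/D snoRNPs, with 591.9, and at l(2)k09022, with 585.3 (odds ratio of the list 26.0, Fisher exact test, adjusted p = 2.01e-16). The RIOK1 peak, on 3L from 11648329 to 11648790, has its summit at 11648520, 46 bp upstream of the RIOK1 start. The Nop56 peak, on 3R from 22420865 to 22421268, has its summit at 22421055 in the 5′ UTR. That summit is also within 500 bp of a start of mats. Of 20 genes for RNA polymerases I and III, 13 had a promoter peak (exact adjusted p = 0.000831). These included Brf, a factor of polymerase III initiation, with a score of 520.7, and Polr1A, the largest subunit of polymerase I, with 322.5. Among cytoplasmic ribosomal proteins RpL7 had a score of 610.2, RpL11 607.9 and RpS27 555.7 (odds ratio of the list 18.0, exact adjusted p = 3.29e-30).

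Mitochondrial ribosomal proteins had 39 of 73 (exact adjusted p = 2.59e-06). The strongest peaks of this list were at mRpS10, with 1174.1, mRpL41, with 916.7, and mRpS23, with 904.3, and mRpS10 shares its peak with Art3. Translation initiation factors had 22 of 44 (exact adjusted p = 0.00196), led by eIF6 with 568.1, eIF4EHP with 510.6 and eIF1 with 373.3. The eIF6 gene is also in the ribosome biogenesis list, and eIF1 shares its peak with RpL28. Aminoacyl-tRNA synthetases had 19 of 32 (exact adjusted p = 0.000246), led by SerRS with 487.0, GlnRS with 479.9 and IleRS with 297.7. SerRS shares its peak with CG17260, IleRS with Hem, and GlnRS with RIOK2 of the ribosome biogenesis list. Chaperones had 12 of 17 (exact adjusted p = 0.000495), with Hsp83 at 275.9, Hsc70-5 at 248.7 and Hsc70-4 at 243.7. Nucleotide synthesis had 12 of 18 (exact adjusted p = 0.000929), with Adsl at 265.2, RnrS at 240.4 and Uck at 179.1. Cell cycle and replication genes had 17 of 32 (exact adjusted p = 0.00236), including the replication origin factors Orc2 at 352.2, dpa at 312.6 and Mcm5 at 242.2.

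Proteasome genes had 16 of 37 (exact adjusted p = 0.0389), with Rpn5 at 298.4, Rpn3 at 292.0 and Prosalpha7 at 214.5. Vacuolar ATPase genes had 15 of 33 (exact adjusted p = 0.0303), with Vha100-2 at 382.9, Vha16-5 at 195.8 and Vha55 at 181.9. Of 10 Myc cofactors and regulators, 6 had a peak (exact adjusted p = 0.0389): among them rept and pont, paired AAA+ helicases, at 590.0 and 374.0, and brm, the SWI/SNF ATPase, at 562.1. The rept peak is shared with mRpL21, the pont peak with Sirt6 and the brm peak with Arl1. From replicate 3 alone (without replicate 2) the calls of the aminoacyl-tRNA synthetases (exact adjusted p = 0.0923), cell cycle genes (0.0923) and Vacuolar ATPase (0.0966) were lost, and from replicate 2 alone (without replicate 3) those of the Myc cofactors (0.180) and Vacuolar ATPase (0.210). In the higher-scoring part of the IDR list the calls of the Myc cofactors (exact adjusted p = 0.132), aminoacyl-tRNA synthetases (0.231), cell cycle genes (0.231), proteasome (0.428) and Vacuolar ATPase (0.428) were lost. The proteasome call was also lost with a 1000 bp window (exact adjusted p = 0.0951) and against genes within 5 kb of a pooled peak (0.111). That of the Myc cofactors was lost under the same settings (exact adjusted p = 0.0640 and 0.0583) and with shared promoters counted once (0.0983). That of Vacuolar ATPase was lost with a 250 bp window (exact adjusted p = 0.0866), against genes within 5 kb of a pooled peak (0.121) and with 1 canonical start per gene (0.0596).

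In the Myc-Max network, 3 of 5 members had a promoter peak, which did not pass the test (exact adjusted p = 0.140). Max itself had a peak on 3L from 19264157 to 19264418 with a score of 330.5, and its summit at 19264324 lies 140 bp upstream of the Max start. That summit is also within 500 bp of starts of CG42374 and Mettl5. The bigmax gene, which encodes the partner of Mondo, had a score of 239.6 and Mnt, a repressor of the network, had 128.9. The bigmax summit is also within 500 bp of a start of Hmu. Neither the Max peak nor the bigmax peak can therefore be assigned to 1 gene alone. The Mnt peak, on X from 3687780 to 3688215, lies in an intron, 237 bp upstream of an internal start. Myc (X, 3373159 to 3391697) and Mondo (2L, 21286078 to 21310050) had no IDR summit at a start. Their starts lie 22 and 35 bp from summits of the pooled list that ranked 14210 and 10972 of 30000, below the IDR list. For Myc the nearest summit was 22 bp away in replicate 2 but 786 bp away in replicate 3, outside the promoter window. For Mondo, which has 3 annotated starts, it was 34 and 22 bp away in replicates 2 and 3.

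Lists that did not pass were glycolysis with 7 of 13 members (highest at Gapdh2, 674.5), oxidative phosphorylation with 24 of 80 (ND-ASHI, 376.9), autophagy with 9 of 22 (Atg2, 326.9), the circadian clock with 6 of 12 (sgg, 322.0), germline with 5 of 17 (bgcn, 204.3), and Hox and segmentation genes with 3 of 31 (nkd, 143.4). Of the tissue markers, neuronal genes had 1 of 20 (elav, 493.3), glial 1 of 10 (moody, 202.4), muscle 2 of 19 (Msp300, 379.7), haemocyte and fat body 1 of 16 (ush, 120.2) and trachea 2 of 9 (trh, 196.4), and none of these passed. Under alternatives some of these lists did pass. Glycolysis was higher with a 250 bp window (exact adjusted p = 0.0224), from replicate 3 alone (0.0145) and with shared promoters counted once (0.00595), autophagy from replicate 2 alone (0.0286) and oxidative phosphorylation with shared promoters counted once (0.0292). Hox and segmentation genes were lower with a 1000 bp window (exact adjusted p = 0.0300), from replicate 3 alone (0.0276) and against genes within 5 kb of a pooled peak (0.0304), and neuronal genes with shared promoters counted once (0.00811). Gut genes lay below the other genes with 1 of 28 (fkh, 282.6, exact adjusted p = 0.00839), a call lost from replicate 3 alone (exact adjusted p = 0.0505) and in the higher-scoring part of the IDR list (0.204). Embryos were whole and collected over 0 to 24 h, so binding limited to 1 tissue or stage could fall below the IDR list. A low share in a list of tissue genes, here or below, therefore does not show that Max-GFP was absent from them.

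Of the remaining lists that lay below the other genes, the cuticle member with a peak was Lcp9 (238.8, exact adjusted p = 5.77e-13), whose summit lies 460 bp from its start and within 500 bp of a start of CG3594. The chemosensory member was Obp99b (121.2, exact adjusted p = 1.06e-27). The eggshell member, Cp190, encodes an insulator protein that the list's name pattern took in, with a score of 559.9 (exact adjusted p = 0.0389). The eggshell call was lost from replicate 3 alone (exact adjusted p = 0.0644), in the higher-scoring part of the IDR list (0.331), with a 250 bp window (0.0941), against genes within 5 kb of a pooled peak (0.111) and with shared promoters counted once (0.129). The list of histones had 3 of 115 (exact adjusted p = 1.32e-10), namely His2Av, His3.3B and His4r, which stand apart from the repeated cluster of replication-dependent copies. Reads of those near-identical copies may not be placed uniquely, so their lack of peaks is uncertain. Against genes within 5 kb of a pooled peak, which left 4 histone genes, 3 of the 4 had a peak, the direction turned and the call was lost (odds ratio 6.61, exact adjusted p = 0.121). Of 69 male accessory gland and sperm genes, Sfp26Ad (220.3) and Mst85C (147.7) had a peak (exact adjusted p = 2.59e-06), with summits 324 and 327 bp from their starts and within 500 bp of starts of other genes. Antimicrobial peptides had an exact adjusted p of 0.00837, and their call was lost with shared promoters counted once (0.0577) and in the higher-scoring part of the IDR list (0.133).

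Where Max-GFP lay relative to genes was the second question. Of the 4712 IDR summits, 2855 lay within 500 bp of a protein-coding start (60.6%, 59.2 to 62.0), 5.28 times the mean of 11.5% after circular shifts. The highest of the 1000 shifts reached 14.2% (permutation test, p = 0.001, the smallest possible). Promoter summits lay a median of 80 bp upstream of the nearest start, and 77.4% were upstream of it. Of the 1857 summits outside promoters, 1263 were in introns (68.0%, 65.9 to 70.1), above the shifted mean of 44.4% and the highest shift of 48.0%. Another 537 were between genes (28.9%), under the shifted mean of 33.9% and near the lowest shift of 28.4%. Coding exons held only 5 of the 1857 (0.269%) against a shifted mean of 15.7%, and 3′ UTRs held 28 (1.51%) against 5.10%. Of the 25288 pooled peaks below the IDR list, 28.3% were at promoters, and of the 10000 lowest-ranked pooled peaks, 18.8%.

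**Figure D2:**
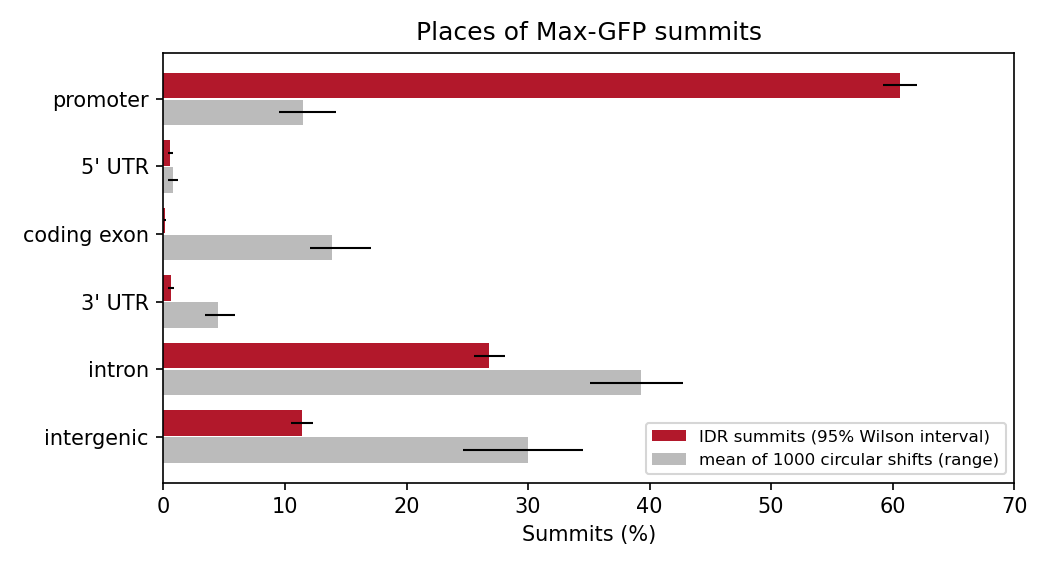
Share of IDR summits in each annotated place (red, with 95% Wilson intervals) and the mean of 1000 circular shifts within arms (grey, bars show their range), in percent. Promoters hold 60.6% of summits against 11.5% after shifts, and coding exons 0.106% against 13.9%; the shares add up to 100%, so a high promoter share lowers the others.

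The strongest promoter peak was at CG14100, on 3L from 19590421 to 19590840, with a score of 1561.5 and its summit at 19590629, 105 bp upstream of the start. It ranked 1 in replicate 3 and 3 in replicate 2. Ugalt, a UDP-galactose transporter, followed with 1393.5 (X, 2703675 to 2704100, summit 29 bp upstream of the start). Chro, which encodes the chromodomain protein Chromator, had 1307.4, with the summit in the 5′ UTR 90 bp inside the transcript. The next were px with 1267.4, PNPase with 1185.2, Art3 with 1174.1, CG18549 with 1004.5, Tcs5 with 995.6, CG9147 with 986.3 and the Polycomb-group gene ph-p with 941.2. None of these 10 peaks had CACGTG within 100 bp of the summit.

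Max binds the palindrome CACGTG, the canonical E-box, as a dimer with Myc or Mnt, and the sequence under the summits was compared with the flanks. CACGTG lay within 50 bp of 164 summits (3.48%, 2.99 to 4.04), against 1.36% and 1.38% in the left and right flanks. The ratio of the summit share to the mean flank share was 2.54 (exact McNemar test, adjusted p = 3.78e-11). Among the 64 palindromic hexamers CACGTG ranked 4 by this ratio, after TTTAAA, AATATT and TTATAA. Among the 24 palindromes with 4 G or C bases it ranked 1, and the next, GTGCAC, had a ratio of 1.49. Promoter peaks held CACGTG at 4.45% of summits against 1.31% in their flanks, and peaks outside promoters at 1.99% against 1.45%, which did not pass (exact McNemar p = 0.306). The share at promoter peaks was higher than at other peaks (odds ratio 2.29, Fisher exact p = 4.29e-06).

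Core promoter motifs lay at the summits more often than in the flanks, by exact McNemar tests whose adjusted p-values ran from 1.16e-64 for TATAAA to 3.97e-07 for Ohler 6. The DNA replication-related element TATCGATA (DRE), the binding site of DREF, lay at 3.52% of summits against 0.308% in the flanks, a ratio of 11.4, the highest of 158 palindromic octamers that had at least 5 flank matches on average. Ohler 1 (GGTCACAC) lay at 2.19% (ratio 6.24), Ohler 7 (CATCNCTA) at 2.36% (ratio 3.64), Ohler 6 (GGTATTTT) at 1.70% (ratio 3.33) and TATAAA at 23.2% (ratio 2.38). The ratio of TATAAA lay within the range of the 8 palindromic hexamers of A and T alone, which ran from 1.80 to 2.73. The GAGA element GAGAGAG was lower at summits than in the flanks, at 1.25% against 2.75% (exact McNemar test, adjusted p = 5.00e-07). Its ratio of 0.456 lay within those of the 23 palindromic hexamers other than CACGTG with 4 G or C bases (0.277 to 1.49). The non-canonical E-boxes CACGCG (2.23%), CATGTG (4.16%) and CAGCTG (4.41%) and the Zelda motif CAGGTAG (0.531%) had ratios from 0.761 to 0.863 and did not pass. Of these CATGTG came nearest to the threshold (exact McNemar test, adjusted p = 0.0544). The mean GC content within 50 bp was 34.7% at IDR summits and 44.6% at 500 bp to the left, while at the summits of the 10000 lowest-ranked pooled peaks it was 41.9%.

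**Figure D3:**
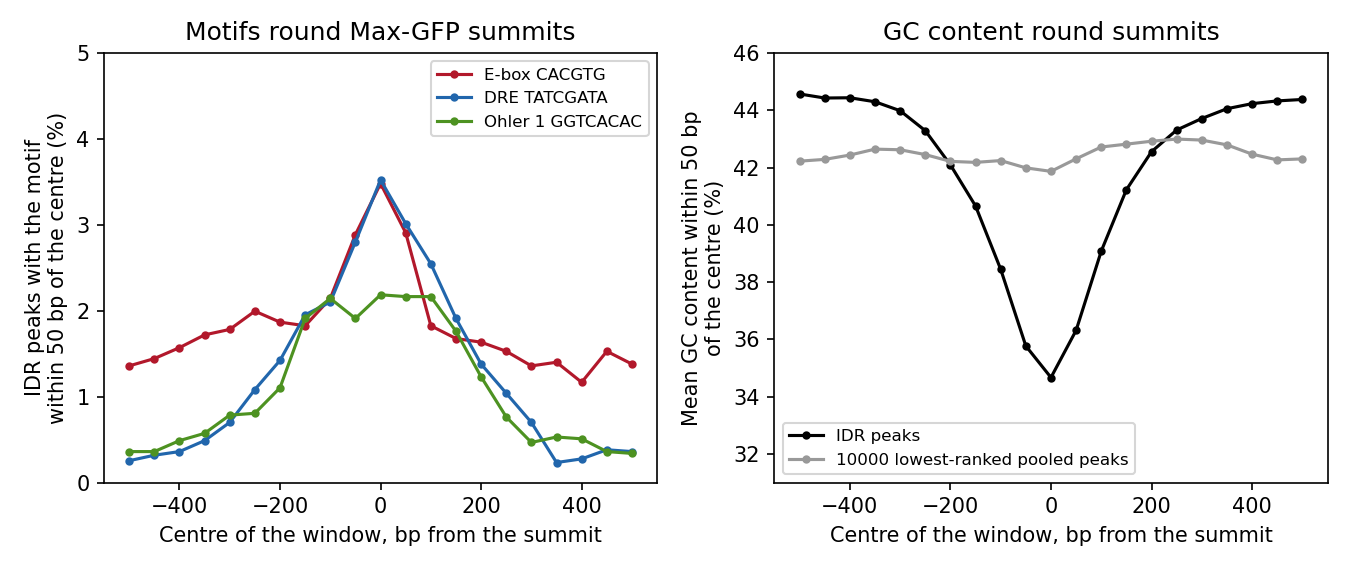
Left, share of the 4712 IDR peaks with the E-box, DRE or Ohler 1 within 50 bp of each position from 500 bp left to 500 bp right of the summit, in percent. Right, mean GC content of the same windows for IDR peaks (black) and the 10000 lowest-ranked pooled peaks (grey), with 34.7% and 41.9% at the summit; the GC axis does not start at 0.

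Stronger peaks held the E-box more often. The IDR list was divided by score into 5 groups of near-equal size. In the highest group 53 of 943 summits had CACGTG within 50 bp (5.62%, 4.32 to 7.28), against 19 of 942 in the lowest (2.02%, 1.29 to 3.13), a ratio of 2.79 (Fisher exact p = 5.50e-05). The shares of the groups between them were 4.35%, 3.50% and 1.91%. The ratio depended on the peaks used: among promoter peaks only it was 5.0 (Fisher exact p = 2.09e-06), and between the highest and lowest 10% of the list 2.07 (Fisher exact p = 0.0345). For the DRE the shares were 3.71% in the highest and 4.25% in the lowest group (Fisher exact p = 0.559), and for Ohler 1 they were 1.70% and 2.87% (Fisher exact p = 0.0923), and neither passed.

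The replicates ranked largely overlapping sites highly. Of the 4712 highest-scoring peaks of replicate 2, 3638 overlapped one of the 4712 highest of replicate 3 (77.2%, 76.0 to 78.4), and in the other direction 75.9% did. After circular shifts the mean was 2.64% (permutation test, p = 0.001, the smallest possible). Over all 30000 peaks the overlap was 61.8% of replicate 2 and 57.1% of replicate 3. Of the IDR peaks, 4689 were matched in both replicate lists, and across these peaks the scores had a Spearman rho of 0.695 (0.679 to 0.712 over 1000 resamples of peaks) and, on the log2 scale, a Pearson r of 0.759. Only 98 of the top peaks of replicate 2 (2.08%) and 82 of replicate 3 (1.74%) overlapped no peak anywhere in the other list.

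Single promoters did differ in rank between the libraries. The peaks at spel1, CG46467, CG17385, FBXO11 and Bhmt ranked between 2288 and 3633 in replicate 2 and between 19819 and 28876 in replicate 3. In the other direction, the peak at Trl, which encodes GAGA factor, ranked 766 in replicate 3 and 11446 in replicate 2, and those at rno, Pfrx, Pu and nxf4 ranked between 1467 and 2613 in replicate 3 and between 9522 and 11938 in replicate 2. With 1 library on each side no test of these differences is possible.

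The peaks were spread over all 6 main arms, and their share on X was close to the share of promoters there. X held 796 IDR peaks (16.9%, 15.9 to 18.0), with 17.0% of promoters (exact binomial p = 0.923), and the small chromosome 4 held 24 (0.509%, 0.343 to 0.757), with 0.748% of promoters (exact binomial p = 0.0620). By the same test, without adjustment over arms, 2R held 18.7% of peaks with 20.8% of promoters (exact binomial p = 0.000306) and 3L held 20.8% with 19.4% (exact binomial p = 0.0175), while 2L (p = 0.836) and 3R (p = 0.136) did not pass. Peak density was 33.8 per Mb on X, 37.2 on 2L, 34.8 on 2R, 34.9 on 3L, 36.1 on 3R and 17.8 on chromosome 4. Per 100 protein-coding genes it was 36.2, 32.9, 30.8, 35.8, 33.8 and 30.0. The share of chromosome 4 lay below that of promoters when only the higher-scoring part of the IDR list was used (0.297%, exact binomial p = 0.00792) and on the dm3 list (0.451%, exact binomial p = 0.0184), so this call depends on the list.

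On dm3 the same libraries gave 4438 IDR peaks, 0.942 times the number on dm6, with a median width of 436 bp on both. The difference of 274 peaks was spread over the arms. X had 752 peaks on dm3 and 796 on dm6, 3R had 1095 and 1158, and chromosome 4 had 20 and 24. Of the dm3 IDR peaks 1 lay outside the main arms, on the mitochondrial genome, and of the dm6 IDR peaks none did.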

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

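The tests of summit placement and of base composition below were chosen after the result was seen, as was the test within 5 groups by score. The tests of promoter peaks, of the annotated starts and of E-box content in the ribosome lists were written before their results were seen.

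On dm3 some peaks lay on sequences other than the 6 main arms: 53 in the pooled list, 55 in replicate 2 and 84 in replicate 3, above the 3 counts that a count of 0 allows. They were not set aside in the counts and overlaps on dm3, and no comparison treats them on their own. The highest ranked 650 in the pooled list with a score of 267.0 and lay on the mitochondrial genome. Most of the others were on heterochromatin sequences assigned to the chromosome arms.

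Few IDR summits held CACGTG. Summits placed up to 200 bp from the motif could account for only a small part of this. Within 200 bp the share of peaks with CACGTG exceeded that of the flanks by 3.79 percentage points (2.84 to 4.74). Low GC content at the summits may contribute, and how far cannot be told from these tables: of the other 23 palindromes with 4 G or C bases 20 were rarer at summits than in the flanks, with a median ratio of 0.591 (exact sign test, p = 0.000488), while CACGTG itself was more frequent at summits. Recovery of active promoters whatever their motif stays open. Promoter peaks held CACGTG 3.39 times as often as their flanks, but flanks 500 bp away are not a set of other promoters. Any sequence common at promoters could exceed them. Over all IDR peaks the core promoter motifs DRE and Ohler 1 did so by more (ratios 11.4 and 6.24) than CACGTG (2.54). The ratio therefore cannot decide, for peaks with the motif or without it, and no IP without Max-GFP was analysed here. Binding through partners or through other motifs could be a further explanation. Of the motifs counted, the non-canonical E-boxes were not more frequent at summits than in the flanks, while the DRE and Ohler 1 were. Low GC content may have lowered the counts of these E-boxes too. CAGCTG, with a ratio of 0.863, lay above the median of 0.591 of the palindromes with 4 G or C bases. Ratios below 1 therefore do not speak against binding at these E-boxes. Whether Max-GFP was bound through any of the motifs counted was not tested.

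Of the gene lists, 12 lay above the other genes at promoter peaks. More annotated starts per gene, and so more chances to lie near a summit, does not account for this, since 11 of the 12 lists still passed with 1 canonical start per gene, an alternative chosen after the data were seen, and only Vacuolar ATPase was lost. Whether higher transcription of these genes in embryos sets the pattern was not tested, because no expression values were analysed here. No biological explanation was tested, since the design has 1 group.

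The E-box differed between the lists of ribosome genes. Among members with a promoter peak, 21 of 36 nucleolar ribosome biogenesis genes and 15 of 74 cytoplasmic ribosomal protein genes had CACGTG within 100 bp of the summit (odds ratio 5.51, Fisher exact p = 0.000164). The biogenesis peaks were also stronger, with a median score of 312.9 against 206.3, a log2 difference of 0.60 (permutation test, p = 0.00864), so strength may contribute a part. Peak strength as the whole cause is argued against by the odds ratio of 4.56 within 5 groups of the IDR list by score (permutation test within the groups, p = 0.00136). A direct role of the E-box at biogenesis genes was not tested and remains a hypothesis.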

How the results depend on the processing

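Of the alternatives, 1 canonical start per gene and 1 row per distinct interval were chosen after the data were seen. The N highest pooled peaks are the IDR list itself, and taking the same part of both IDR lists leaves their ratio fixed, so neither gives information. Over the main results, 52 of 63 alternative values kept their direction and their side of the threshold or stayed near the main value. The Spearman rho fell from 0.695 to 0.664 with summits matched within 100 bp and to 0.674 in the higher-scoring part of the IDR list. The promoter share was 44.7% where the peak's own interval had to hold the start, which asks more of narrow peaks. The E-box ratio of 2.54 passed but fell to 2.08 within 100 bp and 1.67 over all pooled peaks. Within 250 bp, with the flanks 1000 bp away, it passed at 1.62. Outside promoters it was 1.37, not past the threshold. It rose to 3.11 in the higher-scoring part of the IDR list. The ratio between the highest and lowest groups by score was 2.79, 2.07 between the highest and lowest 10% of the list, 2.83 within 100 bp and 5.0 among promoter peaks only, and 3.30 and 3.00 without replicates 2 and 3. In the higher-scoring part of the IDR list 7 lists were higher and 4 lower, in place of 12 and 7, with fewer genes bound. The chromosome 4 share passed as lower in that part (0.297%), on dm3 (0.451%) and against arm length (0.509% of peaks, 1.01% of length). Among the top N/2 peaks, 5 of replicate 2 and 8 of replicate 3 had no match in the other list, from a list of higher-ranked peaks. The cause of the other changes was not tested. Leaving out a replicate gave promoter shares of 58.2% to 61.8%, E-box ratios of 2.24 to 2.38, 10 to 11 lists higher and 6 to 7 lower.

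Odds ratios of lists turned direction as follows, in no case past the threshold under the alternative. With the background within 5 kb of a pooled peak, histones had 6.61, because 4 members were left. With a 1000 bp window glial genes had 1.06. In the higher-scoring part of the IDR list oxidative phosphorylation had 0.963, trachea 1.56 and germline 0.341. Without replicate 2 trachea had 1.502 and germline 0.924, and without replicate 3 germline had 0.876, while trachea kept its direction there (0.813). Of the other single-list values 204 kept their call, 27 lost it and 9 gained it. Depth is unknown, so no limit of detection can be given.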

Other observations

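The tests of motifs by gene list in the next paragraph, other than that between the ribosome lists, were chosen after the data were seen.

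Among 3613 genes with a promoter peak, 12 of the gene lists had at least 10 such genes, and 3 of these held the E-box within 100 bp of the summit more often than the other genes with a peak. These were nucleolar ribosome biogenesis with 58.3% (42.2 to 72.9; adjusted p = 4.27e-14), RNA polymerases I and III with 46.2% (23.2 to 70.9; adjusted p = 0.00125) and cytoplasmic ribosomal proteins with 20.3% (12.7 to 30.8; adjusted p = 0.00148), all by the Fisher exact test. Over all promoter peaks it was 7.67%. The biogenesis genes with the E-box included Fib, Nop56, Nop60B, NHP2, nop5, pit, Nopp140, mod, ppan and bys, and the polymerase genes with it included Polr1A, Polr1B, Polr1C, Polr1E and Polr1H. None of 24 oxidative phosphorylation genes and none of 16 proteasome genes with a peak had it (intervals up to 13.8% and 19.4%), although the DRE was within 100 bp at 5 of those 16 proteasome genes, and no list passed for the DRE. Genes outside the naming rule were named here after their values were seen.

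The median summit lay 14 bp upstream of the start at the 219 promoter peaks with an E-box, 25.5 bp upstream at the 188 with Ohler 1, 41 bp upstream at the 272 with a DRE and 80 bp upstream at all 2855, and these differences were not tested. Of genes with an IDR peak at a start, 6.20% had CACGTG within 100 bp of their canonical start, against 1.77% of the 10331 without (odds ratio 3.67, Fisher exact p = 1.18e-36).

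Genes that do not encode proteins were also compared with the shifted lists. Of 290 tRNA genes, 15 had a summit within 500 bp (5.17%) against a shifted mean of 3.28% (permutation test, p = 0.116). A hypothesis written before the result was that neighbouring protein-coding starts account for summits near tRNA genes, and of the 211 tRNA genes with no such start within 1000 bp, 2.84% had a summit, against 3.27% after shifts (permutation test, p = 0.633), so no signal of their own was detectable. Of 269 snoRNA genes, 27 had a summit (permutation test, p = 0.003), and of the 184 away from coding starts 6 did (permutation test, p = 0.494). Of 3261 genes annotated as ncRNA, 200 had a summit (6.13%) against a shifted mean of 3.35% (permutation test, p = 0.001), and of the 2325 away from coding starts 4.00% did, against 3.34% (permutation test, p = 0.101). Genes of snRNA (permutation test, p = 0.113), rRNA (p = 1) and pseudogenes (p = 0.383) did not pass. Of 5809 transposable element insertions, 56 had a summit within 500 bp of their start (0.964%), against a shifted mean of 3.17%, and reads from repeats may not be placed uniquely.

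Low-ranked peaks of the replicates were spread differently over the arms. Chromosome 4 held 2.02% of the 30000 peaks of replicate 2 and 1.27% of those of replicate 3, and X held 17.4% and 15.6%. Among the 4712 highest peaks the shares were 0.531% and 0.509% for chromosome 4, and 16.3% and 16.9% for X. With 1 library on each side this difference was not tested.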
